A study of Homo sapiens with 4 samples.

How the data were processed

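The samples were 4 RNA-seq libraries of HT8 cells, 2 labelled control and 2 labelled PPDPF knockdown, and each was put in its group by its genotype label. What the names HT8 and HT8-cas1 stand for is not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol, prepared with standard Illumina protocols and sequenced by a commercial provider. The submitters' processing notes name HISAT2 2.0.5 and the build hg18. The authors deposited FPKM per gene, that is, reads scaled by exon length and library size, in 1 table per library. The counting tool, the strand setting and the filters are not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical copies, cannot be told apart.

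All 58735 gene IDs in the tables matched GENCODE 29, whose coordinates are on GRCh38, and none of its genes was missing, so coordinates are given on GRCh38 although the notes name hg18. FPKM multiplied by the union exon length of GENCODE 29 gave whole reads for 100% of the values above 0, within 0.01 of a read. Totals of reads in genes were 17348315 and 19479906 for control replicates 1 and 2, and 17330674 and 17069628 for knockdown replicates 1 and 2. The number by which the authors divided differed from these totals by 1.37%, 0.895%, -0.415% and -0.664%, so their FPKM may include a scaling factor per library. A shift of that size applies alike to each gene of a library. Genes above 0 numbered 23895, 24047, 23761 and 23478. The 10 most abundant genes took 4.48%, 4.41%, 4.08% and 3.97% of the reads, and protein-coding genes took 97.8% to 98.0%.

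The design fixed before the data were examined assumed counts. Since the deposited values were FPKM, its fallback for normalized values was used. Genes with a mean FPKM of at least 1 over the 4 libraries (12777) were tested on log2(FPKM + 1) with limma-trend (limma 3.58.1 in R 4.3.3). The 2 groups were the only term, which left 2 residual degrees of freedom. Two-sided p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Of the 43 gene lists fixed beforehand (33 pathways or complexes and 10 sets of cell type markers), 35 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the 35. The symbols H2AC18 and H3C2 matched no gene ID. Camera with an estimated correlation, which rests on 2 residual degrees of freedom, and fry were the alternatives.

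The rule for named genes, fixed beforehand, took PPDPF and its listed neighbours, up to 4 members with the smallest p per list, and the 12 genes that rose and the 12 that fell with the largest log2 fold change. Some genes that it took are not reported here. The 24 were taken among called genes with a symbol, a mean FPKM of at least 5 and both libraries labelled knockdown on the same side of both controls. Alternatives fixed beforehand were quantile normalization, no filter, a mean FPKM of at least 5, a pseudocount of 0.1, the replicate number as a block, each library left out in turn and stricter thresholds. Alternatives chosen after seeing the data were limma-voom on the recovered reads, scaling to reads outside the mitochondrial genome, protein-coding genes only, removal of the shifted regions, and removal of a loess trend (span 0.5) on GC content and exon length.

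Chromosomal windows held 30 tested genes in steps of 10, over 12745 genes with a position, and the threshold was the 95% quantile of the largest absolute median in 1000 shuffles. The fit was tested on 5 simulated data sets with 200 changed genes each, drawn for the comparison of knockdown against control with 12840 genes tested in the first. It recovered 4.40% of genes changed 1.25-fold, 61.2% at 1.5-fold, 86.0% at 2-fold and 97.6% at 4-fold. False calls numbered 68, which is 9.84% of the calls and above the nominal 5%. A list shifted 1.15-fold was called in 5 of 5 simulations, with 1 call of another list. The simulated genes varied independently, and far fewer changed than were called in the data. The simulations thus do not show how often camera calls lists falsely where members vary together, as for the interferon list (estimated correlation 0.65). Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.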

Results

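RNA from HT8, a human cell line whose tissue the labels give as colon cancer, was sequenced from 4 libraries, 2 of a control group and 2 of a group labelled PPDPF knockdown. PPDPF is the pancreatic progenitor cell differentiation and proliferation factor. The design text sets these 2 groups against each other, so the comparison asks which transcripts differed between them. The deposited values were FPKM for 58735 genes, from which whole read numbers could be recovered. The reads in genes came to 17348315 and 19479906 in the control libraries and to 17330674 and 17069628 in the libraries labelled knockdown. The 2 libraries of each group differed by more than sampling noise, with a chi-square per gene of 2.64 for the controls and 2.47 for the libraries labelled knockdown, so each counted as its own sample. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels below are mean FPKM ± SD over n = 2 libraries per group, and fold changes are those of FPKM + 1 on the log2 scale, which understates the change of low genes.

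PPDPF itself was not lower in the libraries labelled knockdown. PPDPF (ENSG00000125534, GRCh38 chromosome 20, 63520724 to 63522206) had 237 and 266 FPKM in the control libraries and 281 and 283 FPKM in those labelled knockdown, from 4563, 5723, 5297 and 5246 reads. The group means were 252 ± 20.5 in control and 282 ± 1.6 FPKM in the libraries labelled knockdown. This is a fold change of 1.12 (log2 fold change 0.16, SE 0.06) that did not pass the test (limma adjusted p = 0.0940). The value was above 0 in each of 15 other settings and passed the threshold as higher in 5 of them. One was the fit without control replicate 2, with a log2 fold change of 0.25 (limma adjusted p = 0.0233, over all settings 0.00424 to 0.281). Without control replicate 1 it was 0.081 (limma adjusted p = 0.190), so its size rests on which control is kept. Since the targeted gene was not lower, the group is called the libraries labelled knockdown, its 2 libraries knockdown replicates 1 and 2 only after their labels, and each rise or fall is of these libraries relative to control.

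Among the 15 listed neighbours of PPDPF on chromosome 20, 9 were expressed highly enough to test, and 3 rose and 3 fell. PTK6, a non-receptor tyrosine kinase next to PPDPF, rose from 18.9 ± 0.802 to 31.1 ± 0.656 FPKM (1.61-fold, limma adjusted p = 0.00136). SRMS, another kinase of the same family, had a log2 fold change of 0.21, and SLC2A4RG, a transcription factor gene, a fold change of 1.11. HELZ2, a nuclear receptor coactivator, fell to 0.698 of control, EEF1A2, a translation elongation factor, to 0.873, and STMN3, a stathmin, to 0.709. GMEB2, ARFRP1 and ZGPAT did not pass the test, with fold changes of 1.03, 1.08 and 1.05. The calls of SRMS, SLC2A4RG and STMN3 were lost whichever library was left out (limma adjusted p = 0.0648 to 0.162, 0.0640 to 0.122 and 0.0537 to 0.154), and with no filter on low values (0.114, 0.0725 and 0.142). SRMS and SLC2A4RG also lost theirs under quantile normalization (0.0670 and 0.0732) and scaled to non-mitochondrial reads (0.0626 and 0.0588). SRMS did so with voom (0.0919 with the authors' divisor and 0.133 with total reads), and SRMS and STMN3 with the replicate number as a block (0.0705 and 0.0595). EEF1A2 lost its call without knockdown replicate 1 (limma adjusted p = 0.0582), and both EEF1A2 and HELZ2 lost theirs with no filter (0.0667 and 0.0520). CHRNA4, FNDC11, RTEL1 and LIME1 lay under the filter, and TNFRSF6B was listed at 0 in each library.

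**Figure D1:**
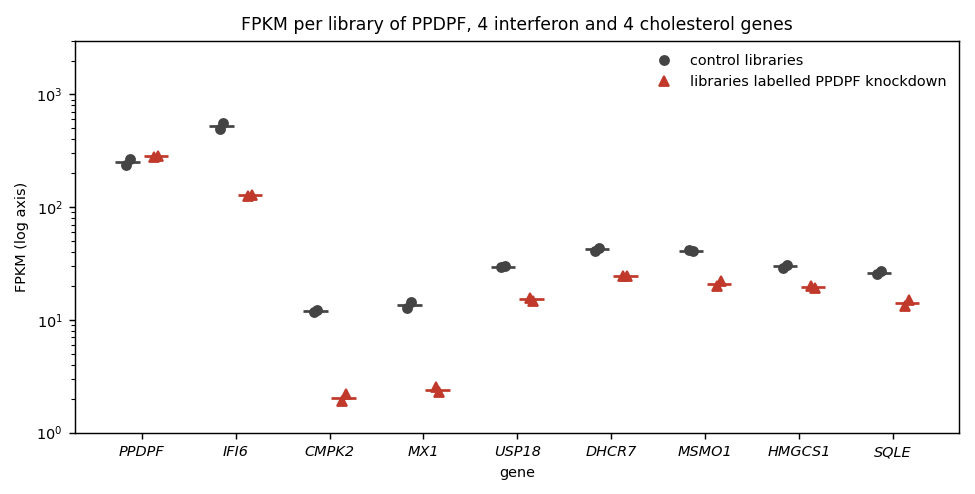
FPKM of each library on a log axis for PPDPF, 4 genes of the interferon list and 4 of the cholesterol list, with circles for the control libraries, triangles for the libraries labelled knockdown and a bar at each group mean. PPDPF stood at 252 against 282 FPKM, while IFI6 stood at 526 against 127 FPKM.

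WNT6, which encodes a secreted Wnt ligand, showed the largest rise among the genes named by the rule. It rose from 0.244 ± 0.204 to 18.8 ± 0.760 FPKM (3 and 13 reads against 568 and 527), a fold change of 16.0 (limma adjusted p = 0.000597). The secreted proteins IL32, a cytokine, TFF1, a trefoil peptide of gastric mucus, and GAST, the hormone gastrin, rose 4.36, 3.86 and 3.14-fold, with TFF1 going from 55.1 ± 1.39 to 215 ± 10.7 FPKM. LY6D and LY6E, GPI-anchored surface proteins, rose 4.01 and 3.12-fold, and both lie in a stretch of chromosome 8 whose genes were higher as a whole. SDCBP2, a syntenin, rose 3.58-fold, CST7, a cysteine protease inhibitor, 3.50-fold, and OLR1, a receptor for oxidised LDL, 3.37-fold. BAMBI, a decoy receptor of TGF-beta signalling, rose 2.93-fold and AHNAK2, a giant scaffold protein, 2.89-fold. LGALS7B, a galectin, rose 3.03-fold, but it has a near-identical paralog and its level is uncertain. These 12 genes had a limma adjusted p between 0.000597 and 0.00219.

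Interferon-induced antiviral genes led the genes that fell, and 5 of the 12 named by the rule belong to the interferon list. IFITM1 fell from 24.4 ± 3.14 to 3.22 ± 0.232 FPKM, to 0.166 of control (limma adjusted p = 0.000685), and BST2, which tethers virions to the cell surface, to 0.189. MX1, CMPK2, IFI6 and OAS2, all known interferon-induced genes, fell to 0.233, 0.234, 0.244 and 0.284 of control, and UBE2L6, the conjugating enzyme of ISG15, to 0.274. IFITM1 lies in a stretch of chromosome 11 that was lower as a whole and has close paralogs. ALDH1A1, a retinaldehyde dehydrogenase, fell to 0.259, SBSPON, an extracellular matrix protein, to 0.269, and EREG, the EGF receptor ligand epiregulin, to 0.339. The mitochondrial tRNA gene MT-TL1 fell to 0.334, though it is short and reads can be shared with the genes beside it. FABP5P7, a pseudogene of FABP5 that can share its reads, fell to 0.265 (limma adjusted p = 0.0125). Its call was lost without control replicate 1 or 2 (limma adjusted p = 0.0603 and 0.0527) and with no filter (0.0768), while the other 11 had a limma adjusted p between 0.000597 and 0.00205.

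Across the 12777 genes tested, 2152 rose and 1662 fell in the libraries labelled knockdown (limma-trend, Benjamini-Hochberg adjusted p under 0.05, two-sided). Protein-coding genes made up 2013 of the genes that rose and 1483 of those that fell. Most changes were small, since the median absolute log2 fold change of the called genes was 0.34 and only 93 of the risen and 97 of the fallen genes reached a log2 fold change of 1 in size. Both libraries labelled knockdown lay on the same side of both controls for 69.7% of the tested genes, where chance gives 33.3%. The libraries of one group correlated with a Pearson r of 0.990 (controls) and 0.991 (labelled knockdown) across genes, and those of different groups with 0.971 to 0.974, and genes are not independent replicates. The counts fell to 1197 and 775 without control replicate 1, 1345 and 822 without control replicate 2, 1141 and 829 without knockdown replicate 1, 1160 and 919 without knockdown replicate 2, and 1134 and 734 with no filter on low values. Which direction had more genes depended on the scaling, since 2502 rose and 2709 fell with voom on total reads, and 1886 and 2029 when scaled to non-mitochondrial reads.

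The interferon response genes fell together. Of 32 tested members of this list, fixed before the data were examined, 0 rose and 29 fell (0 and 30 adjusted over the list alone, camera adjusted p = 4.21e-18, and adjusted p = 0.395 with an estimated correlation). Their median log2 fold change was -0.76. IFI6 fell from 526 ± 45.4 to 127 ± 1.26 FPKM, and CMPK2 from 12 ± 0.451 to 2.05 ± 0.189 FPKM. MX1 fell from 13.6 ± 1.10 to 2.40 ± 0.167 FPKM, and USP18, the protease that removes ISG15, from 29.6 ± 0.258 to 15.2 ± 0.548 FPKM. Among antigen presentation genes, 0 rose and 9 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.00139, and adjusted p = 0.398 with an estimated correlation), of 15 tested. The immunoproteasome subunit PSMB9 fell to 0.416 of control, the peptide transporter genes TAP2 and TAP1 to 0.684 and 0.751, and HLA-F, a class I gene with close paralogs, to 0.691. Shifted chromosomal regions held 4 members of the interferon list and 2 of the antigen presentation list, HLA-F among them.

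Sterol synthesis genes were lower together. In the cholesterol biosynthesis list of 24 tested genes, 0 rose and 20 fell (0 and 20 adjusted over the list alone, camera adjusted p = 9.11e-11, and adjusted p = 0.366 with an estimated correlation), with a median log2 fold change of -0.48. DHCR7, which catalyses the final step to cholesterol, fell from 42.2 ± 1.64 to 24.5 ± 0.197 FPKM, and MSMO1, a sterol methyl oxidase, from 41.1 ± 0.576 to 21 ± 1.62 FPKM. HMGCS1, which makes HMG-CoA, fell to 0.667 of control and the squalene epoxidase SQLE to 0.553. SQLE lies at the start of the chromosome 8 region whose genes were higher as a whole. Windows centred at 125 and 132 Mb had medians of -0.03 and 0.16, so no such shift was shown around SQLE. For fatty acid synthesis, 1 rose and 8 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.00784, and adjusted p = 0.450 with an estimated correlation), of 17 tested genes. The desaturase SCD fell from 101 ± 11 to 44.3 ± 3.26 FPKM, the fatty acid synthase FASN to 0.740 of control, ACLY, which supplies cytosolic acetyl-CoA, to 0.818, and the lipogenic transcription factor SREBF1 to 0.691.

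Metallothioneins, which bind zinc and copper, were lower in the libraries labelled knockdown. Of 8 tested, 0 rose and 7 fell (0 and 7 adjusted over the list alone, camera adjusted p = 4.42e-05, and adjusted p = 0.366 with an estimated correlation), with a median log2 fold change of -0.50. MT1G fell from 82.7 ± 0.235 to 33.7 ± 0.240 FPKM, MT1M to 0.429 of control, MT2A to 0.654 and MT1E to 0.672, with the caution that these near-identical copies can share reads. In the amino acid and ATF4 response list, 2 rose and 13 fell (2 and 14 adjusted over the list alone, camera adjusted p = 0.000195, and adjusted p = 0.373 with an estimated correlation), of 25 tested. PHGDH, the first enzyme of serine synthesis, fell from 47.6 ± 0.112 to 28.9 ± 0.406 FPKM. The tryptophanyl-tRNA synthetase WARS1 fell to 0.547, the pseudokinase TRIB3 to 0.766, and the amino acid transporter SLC7A5 to 0.786. Genes of the ER unfolded protein response numbered 24 tested, of which 2 rose and 10 fell (2 and 12 adjusted over the list alone, camera adjusted p = 0.00187, and adjusted p = 0.450 with an estimated correlation). The transcription factor XBP1 fell to 0.748 of control, SDF2L1 to 0.746, the chaperone HSP90B1 to 0.769 and MANF to 0.809, and the list missed the threshold with fry (fry adjusted p = 0.0509).

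The lists of DNA replication, mitosis and ribosome biogenesis were called lower with small medians, and 26, 24 and 15 of their genes did not pass the test. Of 45 replication and G1/S genes, 1 rose and 18 fell (1 and 19 adjusted over the list alone, camera adjusted p = 2.55e-05, and adjusted p = 0.373 with an estimated correlation), at a median log2 fold change of -0.13. UHRF1, a reader of hemimethylated DNA, fell to 0.685 of control, and the helicase subunits MCM3 and MCM4 to 0.767 and 0.762. In contrast RRM1, a ribonucleotide reductase subunit in a higher region of chromosome 11, rose 1.37-fold. In the G2/M and mitosis list of 44, 1 rose and 19 fell (1 and 21 adjusted over the list alone, camera adjusted p = 8.64e-06, and adjusted p = 0.395 with an estimated correlation), with a median of -0.16. The mitotic activator CDC20 fell from 103 ± 1.18 to 79.1 ± 0.390 FPKM, the cyclin CCNB1 to 0.786, UBE2C to 0.813 and HMMR to 0.754. HMMR lost its call without control replicate 1 (limma adjusted p = 0.0652) and with no filter (0.0641). Ribosome biogenesis gave 30 tested genes, of which 1 rose and 14 fell (1 and 17 adjusted over the list alone, camera adjusted p = 2.15e-05, and adjusted p = 0.366 with an estimated correlation), at a median of -0.14. The nucleolar proteins NOLC1 and NCL fell to 0.815 and 0.844 of control, the pseudouridine synthase DKC1 to 0.790 and the helicase DDX21 to 0.838.

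The proteasome, heat shock and p53 lists were called higher. Of 29 proteasome subunits, 22 rose and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 6.84e-07, and adjusted p = 0.366 with an estimated correlation), with a median log2 fold change of 0.19. PSMC2, which lies in a higher region of chromosome 7, rose 1.44-fold, and PSMB2, PSMB7 and PSMD3 rose 1.27, 1.23 and 1.18-fold. The heat shock list had 17 tested genes, of which 9 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.000144, and adjusted p = 0.366 with an estimated correlation). The small heat shock protein HSPB1 rose from 129.7 ± 1.22 to 231 ± 0.790 FPKM, and HSP90AA1 rose 1.37-fold. HSF1, the heat shock transcription factor, and HSPH1 rose 1.75 and 1.64-fold and lie in higher regions of chromosomes 8 and 13. For p53 targets, 14 rose and 1 fell (17 and 3 adjusted over the list alone, camera adjusted p = 0.000109, and adjusted p = 0.395 with an estimated correlation), of 27 tested. TP53INP1 rose from 8.90 ± 0.224 to 14.8 ± 0.187 FPKM, and FDXR, ZMAT3 and PHLDA3 rose 1.38, 1.37 and 1.48-fold.

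The lists of immediate early, NF-kB and cytokine, hypoxia, and mesenchymal and EMT genes were also called higher, each with genes that did not pass the test. Among immediate early genes 10 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.00123, and adjusted p = 0.373 with an estimated correlation), of 17 tested. The Krüppel-like factors KLF6 and KLF2 rose 1.62 and 1.49-fold, ZFP36, which destabilises AU-rich mRNAs, 1.48-fold and the phosphatase DUSP1 1.35-fold. In the NF-kB and cytokine list of 19, 11 rose and 3 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.00504, and adjusted p = 0.373 with an estimated correlation), and the call was lost with only genes of mean FPKM of at least 5 (camera adjusted p = 0.163). LTB, a TNF family cytokine, rose from 0.361 ± 0.276 to 5.52 ± 0.470 FPKM. BIRC3 and TNFAIP3, both feedback regulators of NF-kB, rose 2.00 and 2.38-fold, and the cyclooxygenase PTGS2 fell from 22 ± 0.506 to 8.04 ± 0.814 FPKM. Of 18 hypoxia genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.000698, and adjusted p = 0.366 with an estimated correlation). NDRG1 of the chromosome 8 region rose 2.02-fold, P4HA2 1.54-fold, EGLN1 1.4-fold and BNIP3L 1.35-fold. Of 11 mesenchymal and EMT genes, 7 rose and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000332, and adjusted p = 0.373 with an estimated correlation). The matrix gene TNC rose from 0.499 ± 0.0786 to 4.30 ± 0.0151 FPKM, and the receptors PLAUR and CD44 rose 1.49 and 1.66-fold.

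The list of enterocyte and colonocyte markers was called higher, at a median log2 fold change of 0.62. Of 11 tested, 8 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00485, and adjusted p = 0.451 with an estimated correlation). The galectin LGALS4 rose from 44.7 ± 2.98 to 69.2 ± 1.56 FPKM and the intestinal alkaline phosphatase ALPI from 6.30 ± 0.198 to 12.5 ± 1.29 FPKM. The keratin KRT20 rose from 0.528 ± 0.267 to 2.77 ± 0.236 FPKM and the intestinal transcription factor CDX1 from 3.45 ± 0.398 to 5.98 ± 0.0662 FPKM. Among 8 goblet and secretory markers, 4 rose and 3 fell (4 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.675). TFF1 and SPINK4 rose 3.86 and 1.66-fold, while AGR2, a disulfide isomerase, fell to 0.633 of control and the trefoil peptide TFF3 to 0.458, a call lost with no filter (limma adjusted p = 0.0556). With only genes of mean FPKM of at least 5, the enterocyte list missed the threshold (camera adjusted p = 0.243).

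**Figure D2:**
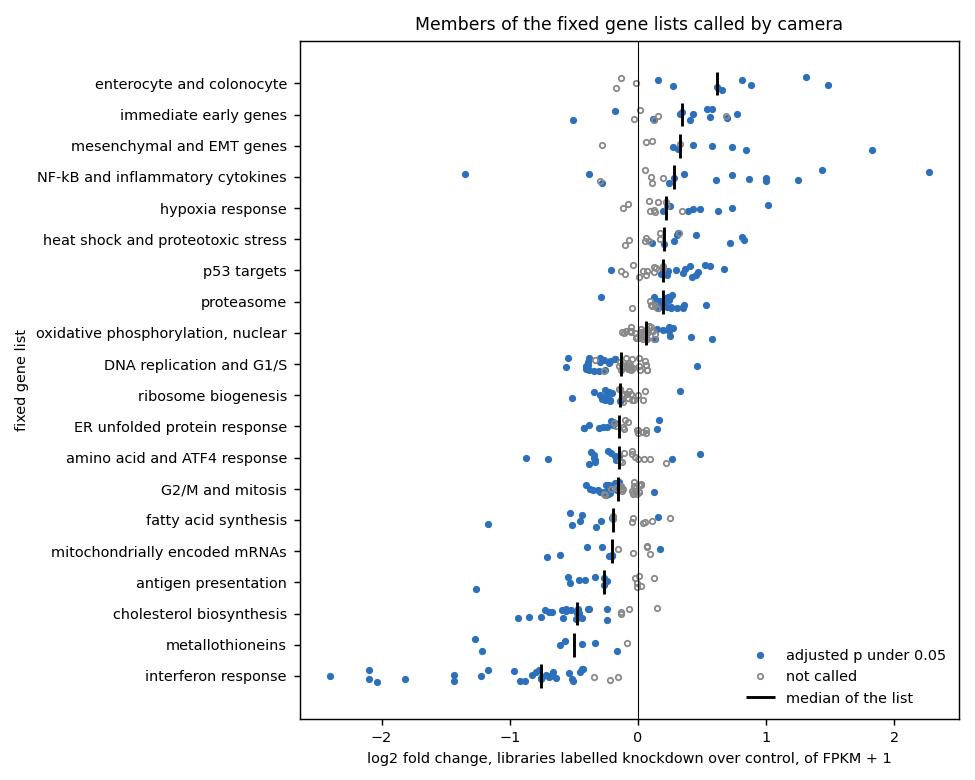
Log2 fold change of FPKM + 1, libraries labelled knockdown over control, for each tested member of the 20 fixed lists called by camera, with filled points for genes past the threshold, open points for the rest and a bar at each list's median. The medians run from -0.76 for the interferon response to 0.62 for the enterocyte and colonocyte list.

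The lists of nuclear and mitochondrial genes of the respiratory chain were called in opposite directions, and both calls were lost in several settings. Of 40 nuclear oxidative phosphorylation genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.460 with an estimated correlation), at a median log2 fold change of 0.06. CYC1 of the chromosome 8 region, NDUFB3, ATP5PB and SDHA of the chromosome 5 region rose 1.49, 1.33, 1.18 and 1.21-fold. ATP5PB lost its call without knockdown replicate 1 and SDHA without control replicate 1 (limma adjusted p = 0.0503 and 0.0566). Of 13 mitochondrially encoded mRNAs, 1 rose and 7 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0196, and adjusted p = 0.598 with an estimated correlation), at a median of -0.20. MT-CO1 fell from 4285 ± 224 to 2814 ± 138 FPKM, MT-ND1 to 0.611 of control, MT-CO2 to 0.759 and MT-CO3 to 0.870. Mitochondrial genes took 2.87% and 2.76% of the reads in the control libraries and 2.35% and 2.19% in those labelled knockdown. The direction of the mitochondrial list and of MT-CO2 turned under quantile normalization (camera adjusted p = 0.730 and log2 fold change 0.04), and MT-CO3 came to no difference there. That normalization gives genes of equal rank the same value in each library, so for such abundant genes it cannot decide whether they fell. The nuclear list lost its call under quantile normalization and with voom on total reads (camera adjusted p = 0.0761 and 0.0739). The mitochondrial list lost its call with no filter (camera adjusted p = 0.124) and with fry (fry adjusted p = 0.118). MT-CO1, MT-CO2 and MT-CO3 lost their calls with no filter (limma adjusted p = 0.132, 0.265 and 0.557). Without knockdown replicate 2 both lists missed the threshold (camera adjusted p = 0.0626 and 0.106), and MT-CO3 did so there and without control replicate 1 (limma adjusted p = 0.0501 and 0.0522).

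In all, 20 of 35 lists tested were called by camera with its preset correlation, 9 higher and 11 lower. Of these, 18 were also called by fry, which asks only whether a list's genes move on balance one way. With correlations estimated from the residuals, 0 lists were called, the lowest adjusted p was 0.366, 4 lists had an unadjusted camera p under 0.05, and fry called 24 lists. The other 15 lists were not called.

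Several signalling lists held called genes without a call for the list. For MAPK/ERK output, 10 rose and 4 fell of 19 tested (10 and 5 adjusted over the list alone, camera adjusted p = 0.0705). There the stress gene IER3 rose from 59.6 ± 2.43 to 132 ± 0.152 FPKM and the phosphatase DUSP5 1.92-fold, while EREG and the ERK inhibitor SPRED1 fell to 0.339 and 0.369 of control. This list passed the threshold with no filter (camera adjusted p = 0.0153) and with a mean FPKM of at least 5 (0.0471), and in 3 further settings, fry among them. Of Wnt/beta-catenin targets, 9 rose and 6 fell of 22 tested (9 and 7 adjusted over the list alone, camera adjusted p = 0.332). BAMBI, APCDD1, CD44 and NOTUM rose 2.93, 3.58, 1.66 and 2.78-fold. APCDD1 and NOTUM are known inhibitors of Wnt signalling. Among STAT3 targets, 4 rose and 0 fell of 13 tested (4 and 0 adjusted over the list alone, camera adjusted p = 0.191). The kinase PIM1 rose 2.58-fold, and the receptors IL6ST and IL4R 1.58 and 1.51-fold. The survival factor MCL1 had a fold change of 1.09 and lost its call whichever library was left out (limma adjusted p = 0.0866 to 0.155), with no filter (0.0898), under quantile normalization (0.131), scaled to non-mitochondrial reads (0.0974) and with the replicate block (0.0663). For RAS and PI3K/mTOR components, 8 rose and 2 fell of 30 tested (8 and 2 adjusted over the list alone, camera adjusted p = 0.285). RHEB of a chromosome 7 region rose 1.54-fold, ERBB2 1.21-fold and NRAS 1.18-fold. NRAS lost its call without control replicate 1 or knockdown replicate 2 (limma adjusted p = 0.0549 and 0.0576).

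Of TGF-beta targets, 2 rose and 2 fell of 13 tested (2 and 2 adjusted over the list alone, camera adjusted p = 0.490). The integrin ITGB6 rose 1.98-fold, while ID3 fell to 0.587 of control and PMEPA1 to 0.706. PMEPA1 lost its call whichever library was left out (limma adjusted p = 0.0721 to 0.143), with no filter (0.131) and with the replicate block (0.0677). ID3 lost its call without knockdown replicate 2 (limma adjusted p = 0.0595) and with no filter (0.0774). The median of this list was -0.07 and camera's direction down, while fry's was up. Of YAP/TEAD targets, 3 rose and 6 fell of 20 tested (6 and 8 adjusted over the list alone, camera adjusted p = 0.563). LATS2 of a chromosome 13 region rose 1.56-fold, and NT5E, FJX1 and ARHGEF17 fell to 0.566, 0.508 and 0.775 of control. ARHGEF17 lost its call without control replicate 1 (limma adjusted p = 0.0569). Of epithelial adhesion genes, 11 rose and 6 fell of 27 tested (11 and 7 adjusted over the list alone, camera adjusted p = 0.422). The list had a median of -0.01 but a mean of 0.03 and camera's direction up. The desmosome genes DSP, DSG2 and JUP rose 1.46, 1.42 and 1.34-fold, and the claudin CLDN2 fell from 3.72 ± 0.181 to 0.635 ± 0.153 FPKM.

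Of the apoptosis regulators, 9 rose and 2 fell of 26 tested (10 and 4 adjusted over the list alone, camera adjusted p = 0.192). BAX and APAF1, both of the mitochondrial apoptosis pathway, rose 1.23 and 1.44-fold, and BIK rose 1.42-fold, a call lost with no filter (limma adjusted p = 0.0550). Among autophagy and lysosome genes, 7 rose and 5 fell of 28 tested (10 and 5 adjusted over the list alone, camera adjusted p = 0.285). The protease CTSB, the receptor SQSTM1 and GABARAPL1 rose 1.64, 1.36 and 2.43-fold, and CTSD of the lower chromosome 11 region fell to 0.723 of control. For glycolysis, 6 rose and 2 fell of 22 tested (6 and 3 adjusted over the list alone, camera adjusted p = 0.285). The lactate transporter SLC16A3 rose 1.72-fold, PGK1 1.20-fold and the glucose transporter SLC2A1 1.23-fold, and the hexokinase HK2 fell to 0.838 of control. Among NRF2 targets, 5 rose and 6 fell of 21 tested (9 and 7 adjusted over the list alone, camera adjusted p = 0.680). The ferritin FTH1, a gene with many pseudogenes, rose 1.42-fold and TXNRD1 1.43-fold, while GPX2 fell to 0.610 of control and TALDO1 of the lower chromosome 11 region to 0.75.

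Ribosomal protein genes were not called as a list. Among them 7 rose and 14 fell of 70 tested (7 and 14 adjusted over the list alone, camera adjusted p = 0.422), at a median log2 fold change of -0.03. The 3 with the smallest p lay in shifted regions in the direction of the region, RPLP2 on chromosome 11 at 0.688 of control, RPL8 on chromosome 8 at 1.53 and RPL21 on chromosome 13 at 1.38. RPL10A fell to 0.842, a call lost with no filter (limma adjusted p = 0.0663), and pseudogenes make levels in this family uncertain. Of the replication-dependent histones, 1 rose and 2 fell of 9 tested (1 and 2 adjusted over the list alone, camera adjusted p = 0.285). H2AC11 of the lower chromosome 6 region stood at 0.630 of control, H1-2 at 0.863, H2BC4 at 1.30 and H3C10, which did not pass the test, at 0.795. The calls of H1-2 and H2BC4 were lost whichever library was left out (limma adjusted p = 0.0505 to 0.116 and 0.0630 to 0.123), with no filter (0.0908 and 0.113), and with voom (0.116 and 0.178 with the authors' divisor, 0.0803 and 0.200 with total reads). H1-2 also lost its call with the replicate block (limma adjusted p = 0.0511). H3C10 passed the threshold without knockdown replicate 2 and with protein-coding genes only (limma adjusted p = 0.0444 and 0.0438). H2AC11 lost its call without control replicate 1 or knockdown replicate 1 (limma adjusted p = 0.0876 and 0.0658) and with no filter (0.0865). The neighbours of PPDPF were not called as a list either (camera adjusted p = 0.715, 3 and 3 genes adjusted over the list alone).

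Markers of other cell types, squamous epithelium apart, averaged under 2 FPKM in each library, and 8 lists had too few tested members for a list test. The mean FPKM of 15 leukocyte markers was 0.312 and 0.304 in control against 0.191 and 0.202 in the libraries labelled knockdown. Neural markers averaged 0.0547 and 0.0453 in control against 0.0560 and 0.0580 and enteroendocrine markers 0.0633 and 0.0517 in control against 0.0463 and 0.0317. Erythroid markers averaged 0.00533 and 0.00390 in control against 0 and 0. No member of these 3 lists passed the filter. Fibroblast markers averaged 1.62 and 1.55 in control against 1.66 and 1.81 and hepatocyte markers 0.589 and 0.558 in control against 0.491 and 0.492. Endothelial markers averaged 1.43 and 1.42 in control against 1.88 and 1.90. In these lists ESAM and EGFL7, endothelial markers, had fold changes of 2.16 and 1.17, and CD14 of monocytes fell to 0.695 of control. CORO1A, COL6A1 and SERPINA1 did not pass the test at 0.815, 1.10 and 0.886. All 3 passed the threshold with voom (limma adjusted p = 0.0485, 0.0193 and 0.0489 with the authors' divisor, 0.0383, 0.0461 and 0.0278 with total reads), and SERPINA1 with protein-coding genes only (0.0485). Calls were lost for CD14 whichever library was left out (limma adjusted p = 0.0769 to 0.135), with no filter (0.112) and with the replicate block (0.0543). For ESAM they were lost without knockdown replicate 1 or 2 (limma adjusted p = 0.0553 and 0.0524) and with no filter (0.0708). EGFL7 lost its call without control replicate 2, knockdown replicate 1 or knockdown replicate 2 (limma adjusted p = 0.0962, 0.0849 and 0.108) and with no filter (0.0794). Squamous markers averaged 11.1 and 11.8 in control against 15.3 and 14.6, with SFN rising 1.33-fold and KRT17 falling to 0.625 of control. KRT17 lost its call without control replicate 2 or knockdown replicate 2 (limma adjusted p = 0.0602 and 0.0540) and with no filter (0.0717). S100A2 and KRT13 did not pass the test, at 1.11 and 0.981.

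Stretches of several chromosomes differed as a whole between the groups, a comparison chosen after the data had been seen. Medians of the log2 fold change were taken over windows of 30 neighbouring tested genes. Of 1219 windows, 60 passed 0.22 in size, the level that the largest median stayed under in 95% of 1000 shuffles of the genes. Joined, they made 14 regions, 11 higher and 3 lower. The end of chromosome 8 (125 to 145 Mb) had a median of 0.49 over 90 genes, of which 66 rose and 4 fell. On chromosome 7, 240 genes between 87.2 and 139 Mb had a median of 0.26, and 2 further regions reached to 152 Mb with medians of 0.24 and 0.22. Chromosome 13 held 4 higher regions with medians of 0.33, 0.25, 0.25 and 0.27, some of which overlap at their ends. The windows between the regions of chromosome 13 had medians of 0.17 to 0.22, and between those of chromosome 7 0.10 to 0.22. How many regions these 2 chromosomes hold thus depends on the threshold. Chromosome 5 had one at 0.197 to 36.2 Mb with 0.28, and chromosome 20 one at 55.1 to 62.8 Mb with 0.24, which ends before PPDPF. The shift faded towards PPDPF, as the chromosome 20 windows centred at 61.5, 63.0 and 63.4 Mb had medians of 0.17, 0.14 and 0.12. These were under the level of the shuffles but above 0. On chromosome 11 the first region (0.168 to 3.64 Mb) was lower, with a median of -0.46, and 47 of its 70 genes fell and 8 rose. The next (2.88 to 6.68 Mb) was higher with 0.36. These 2 regions overlap between 2.88 and 3.64 Mb, and the genes there were counted in both, so where the lower stretch ends is not fixed by them. The other lower regions were on chromosome 1 (235 to 248 Mb, -0.24) and chromosome 6 (27.1 to 30.1 Mb, -0.16). On chromosome 1, 17 of 40 genes fell and 1 rose. On chromosome 6, 7 of 40 fell and 3 rose, a smaller share called than the 29.9% of all tested genes. The bounds given are outer edges of windows, so a region can hold genes that did not shift. Chromosome 1 windows centred at 238, 241 and 242 Mb had medians of -0.03, -0.22 and -0.32. The fall there thus lay towards the region's end.

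Both libraries labelled knockdown shared these shifts. On chromosome 8 they lay 0.52 and 0.50 above the control mean, where the difference of control replicate 2 from control replicate 1 was -0.01. For the lower part of chromosome 11 the values were -0.46 and -0.48, with 0.00 between the controls. The regions held 850 of the tested genes with a position (6.67%) and 12.6% of the calls, 389 higher and 90 lower. With these genes left out, each of the 20 called lists kept its call.

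**Figure D3:**
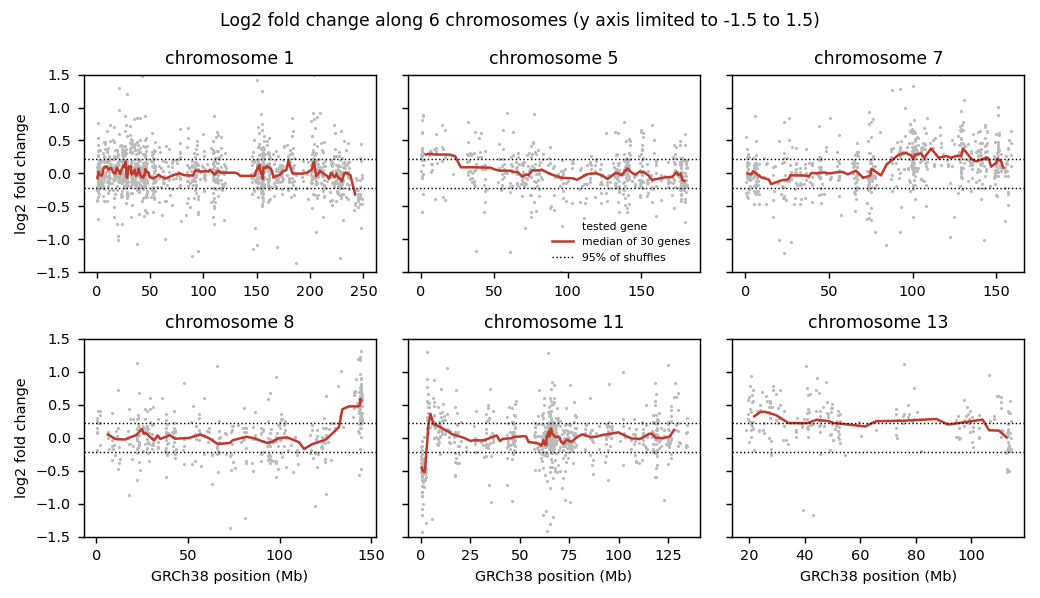
Log2 fold change of each tested gene (grey) and the median of windows of 30 genes (line) against GRCh38 position in Mb on 6 chromosomes, with dotted lines at 0.22 above and below 0, the level from 1000 shuffles. The line leaves these limits at the end of chromosome 8, on the long arm of chromosome 7, along chromosome 13 and at the starts of chromosomes 5 and 11, and 13 genes lie outside the axis limits of 1.5 in size.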

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

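The alternatives on recovered reads, non-mitochondrial scaling, protein-coding genes, shifted regions and the GC and length trend were chosen after seeing the data, and the rest were planned. The genes that rose and fell numbered 1948 and 1883 after quantile normalization, 1999 and 1485 at a mean FPKM of at least 5, and 2142 and 1660 with a pseudocount of 0.1. With no filter they numbered 1134 and 734, and without 1 library 1141 to 1345 and 775 to 919, of which 93.3% to 96.2% and 90.6% to 93.2% were among the genes called before. The fits without 1 library leave 1 residual degree of freedom and assume that the lone library varies like the others. An adjusted p under 0.01 left 927 and 589, and a log2 fold change of at least 1 in size 93 and 97. Voom on the recovered reads, whole for 100% of values, called 2790 and 2373 with the authors' divisor, and 2502 and 2709 with total reads, and scaling to non-mitochondrial reads gave 1886 and 2029. Protein-coding genes alone gave 2521 and 2024, leaving out shifted regions 1710 and 1533, and removing the GC and length trend 2065 and 1804. The planned edgeR quasi-likelihood test on counts was not run, since the values are normalized.

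PPDPF stayed above 0 in 15 of 15 alternatives (log2 fold change 0.081 to 0.25, limma adjusted p = 0.00424 to 0.281; leaving out 1 library gave the whole of that range of fold changes). It passed the threshold as higher at a mean FPKM of at least 5 (0.16, adjusted p = 0.0459), with protein-coding genes only (0.16, 0.0310), without control replicate 2 (0.25, 0.0233), and with voom on the authors' divisor (0.16, 0.00424) or total reads (0.14, 0.0105). At a mean FPKM of at least 5 and with protein-coding genes only, the SE also fell from 0.058 to 0.054 and 0.051. Leaving out the shifted regions gave a limma adjusted p of 0.0981. That setting dropped only 850 genes, which held 12.6% of the calls. It therefore cannot decide whether fewer tests brought the passes. The cause of the passes was not tested.

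Camera called 18 to 21 lists in the other settings, but 0 with an estimated correlation, and fry called 24, of which 18 were among the 20. Nuclear oxidative phosphorylation lost its call under quantile normalization, without knockdown replicate 2 and with voom on total reads (camera adjusted p = 0.0761, 0.0626 and 0.0739). The mitochondrial list turned upward under quantile normalization (adjusted p = 0.730) and lost its call with no filter, without knockdown replicate 2 and with fry. Lists not called before passed the threshold in 10 values, of which 5 were of MAPK/ERK output and the others, all with fry, of apoptosis regulators, RAS and PI3K/mTOR components, STAT3 targets, Wnt targets and PPDPF neighbours. Of 354 alternative values of the 24 genes with the largest changes, 351 kept call and direction. The 24 had been taken for large called changes in these same libraries, so that count does not test them afresh. Of the other named genes, MT-CO2 turned to 0.038 under quantile normalization, which sets values by rank. Leaving out 1 library turned 4 genes that had not passed the test, and the cause was not tested. KRT13 ran from -0.14 to 0.082 (0.047 without knockdown replicate 2), S100A2 from -0.0030 to 0.30, GMEB2 from -0.0072 to 0.081 and ZGPAT from -0.012 to 0.17.

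The replicate numbers were not shown to pair the libraries, as the deviations of same-numbered libraries had a correlation of -0.00206 over 2 pairs. With the number as a replicate block, 1899 genes rose and 1405 fell, PPDPF had 0.16 (limma adjusted p = 0.0723) and 20 lists were called. The block leaves 1 residual degree of freedom and ended the calls of SRMS, STMN3, CD14, H1-2, MCL1 and PMEPA1 (limma adjusted p = 0.0511 to 0.0705), with their fold changes unchanged. In the simulated data the smallest changes were mostly missed (4.40% recovered).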

Other observations

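The genes TFF2, ALDH1A3, FABP5, ABCB1, CAV1 and PLEC, the comparisons drawn with them, and the tests of explanations for the 3 patterns, were chosen after the values had been seen. The trefoil peptides, whose genes lie side by side on chromosome 21, did not move together. TFF1 rose 3.86-fold, while TFF2 fell from 11.9 ± 2.68 to 4.62 ± 1.20 FPKM (limma adjusted p = 0.0127, and 0.0765 with no filter) and TFF3 fell to 0.458 of control (with no filter 0.0556). The retinaldehyde dehydrogenases also parted, as ALDH1A1 fell to 0.259 of control and ALDH1A3 rose from 1.93 ± 0.236 to 5.88 ± 0.865 FPKM (limma adjusted p = 0.00285). FABP5, a fatty acid binding protein, fell from 16.8 ± 1.52 to 6.64 ± 0.282 FPKM (limma adjusted p = 0.00131), in the same direction as its pseudogene FABP5P7, and the 2 can share reads. ABCB1, a drug efflux pump, and CAV1, the main coat protein of caveolae, lie on the shifted arm of chromosome 7 and rose 2.40 and 2.82-fold. PLEC, the cytolinker plectin on chromosome 8, rose from 52.3 ± 3.29 to 122 ± 7.22 FPKM (limma adjusted p = 0.00107).

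The first pattern is that PPDPF was not lower in the libraries labelled knockdown. An exchange of the group labels with a weak knockdown cannot be told apart from a knockdown that did not work. The ratio of the libraries labelled control to the others was 0.892, with a 95% interval of 0.805 to 0.990. This is the direction that an exchange predicts, but PPDPF did not pass the test (limma adjusted p = 0.0940). The direction is not particular to PPDPF, whose log2 fold change was 0.16. The chromosome 20 windows centred at 63.0 and 63.4 Mb had medians of 0.14 and 0.12. Of its 9 tested neighbours, however, 3 rose and 3 fell. Whether the rise is that of the neighbourhood was not tested. Even with exchanged labels this interval reaches no lower than 0.805, so a large fall of PPDPF mRNA is argued against under either labelling. A fall hidden by the authors' divisor is argued against, since it differed from the reads in genes by at most 1.37%. The lowest log2 fold change over 3 other scalings was 0.13 (0.08 to 0.19 within 1 SE). All of these scalings take the libraries as alike in total, so a difference in total RNA between the groups was not tested. That the mRNA stayed, at 1.12 of control, while the protein was reduced cannot be told apart from a knockdown that did not work, because protein was not measured.

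The second pattern is the 14 regions shifted as a whole. Chance order of the genes is argued against, since the largest observed median, 0.59 in size, was above the largest of 1000 shuffles, 0.29 (permutation p = 0.001, the smallest they can give). GC content and exon length are argued against as the whole cause, since each region kept at least 96.9% of its median once their trend was removed, though that trend explained only 0.148% of the variance. A candidate explanation is that the cells of the 2 groups differ in copies of these regions, as the genes too low for the main test shifted in the direction of their region in 13 of 14. In both libraries labelled knockdown they did so in 11. The 14 regions are not independent units, since chromosomes 7, 11 and 13 each held more than 1. Some on chromosomes 11 and 13 overlap, and genes there count in both, so these counts overstate the support. It is also uneven, since the genes too low for the main test had log2 ratios of only 0.04, -0.02 and 0.05 in the regions of chromosomes 5, 6 and 20, where the regions' medians were 0.28, -0.16 and 0.24. They moved more than the median in others, at -0.68 against -0.24 on chromosome 1, 0.75 against 0.22 in the last region of chromosome 7 and 0.53 against 0.27 in that of chromosome 13. The chromosome 1 median also takes in genes at the region's start that were not lower as a whole. In the higher region of chromosome 11, whose median was 0.36, they went the other way, at -0.04 (-0.08 and -0.0029 in the 2 libraries). On chromosomes 5 and 6 the 2 libraries differed in sign (0.09 and -0.02, 0.01 and -0.05). Regulation of whole regions stays open, since DNA was not measured.

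The third pattern is the fall of the interferon genes. Members that lie in the shifted regions do not account for it, as the 28 members outside them had a median log2 fold change of -0.75 (bootstrap 95% interval over genes -0.85 to -0.65). Whether genes in the regions affect members elsewhere was not tested. It does not rest on one library, as the call was kept in 4 of 4 fits without 1 library (camera adjusted p = 1.20e-21 to 4.68e-18), although it is lost with an estimated correlation (adjusted p = 0.395). Whether PPDPF knockdown or a difference between cell populations grown apart lies behind it cannot be told apart. The labels name no second knockdown or control population, and regions holding 6.67% of the tested genes also separate the groups. A second knockdown or control population would bear on this, and a biological effect of the knockdown stays among the open explanations.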
